A study of Mus musculus with 9 samples.

How the data were processed

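RNA from the centre of the cornea was measured on Affymetrix arrays in adult male mice of 3 inbred strains, C57Bl/6J (B6), C57BLKS/J (KS) and SJL/J (SJL). The labels give KS a thin cornea and SJL a thick cornea, and they give B6 no thickness. Per the labels, the mice were 4 months old, a 2-mm punch was taken from each eye, and the 2 punches of a mouse were combined, so each of the 9 arrays stood for 1 mouse. Per the labels' protocols, RNA was treated with DNase, purified on a column and labelled with biotin.

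The deposited values were probe set intensities on a linear scale, which the authors had already summarised over the probes of each probe set. The upper quartiles of the 9 arrays lay between 380 and 396, so the deposited intensities had been brought close to one another before deposit. The method of summary, background correction and scaling is not given in the sources used here. The table held 45101 probe sets, of which 64 were array controls. Intensities ran from 3.39 to 37501 with a median of 7.48, and 54.6% of them lay below 16, close to the lower end of the scale. No detection calls were used, so a level near that lower end is an upper bound on a transcript rather than a measured amount. Array data have no read depth, and 3 arrays per strain set the precision.

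Of the 45037 probe sets that were not controls, 34945 had 1 gene symbol in the platform annotation, 932 had several and 9160 had none. A RefSeq gene table of the assembly GRCm38.p6 held 34741 of the single symbols and changed 0 of them, and it was used only for names and for the order of genes along chromosomes. A gene was represented by its probe set with the highest mean over the 9 arrays among those with that 1 symbol. This gave 18194 genes, of which 10956 had their probe set tested.

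The design allowed for values on a log scale or on a linear scale. The values were linear, so log2(intensity + 10) was analysed, and every log2 difference is on that scale, which understates the change of low genes. Probe sets whose mean log2 value lay below the median of all non-control probe sets were left out, which left 22519. A model with 1 mean per strain was fitted to the 9 arrays with limma 3.58.1 in R 4.3.3, with 6 residual degrees of freedom and a median of 8.41 after variance moderation. The contrasts were SJL against KS, KS against B6 and SJL against B6, with a moderated F-test for any difference among the strains. P-values were adjusted by the Benjamini-Hochberg method over the probe sets tested, and called means an adjusted p under 0.05. All limma tests were two-sided. An exact permutation test of 3 arrays against 3 cannot go below 0.1, so single genes were tested only through the limma model. Levels are given as means ± SD of intensity with n = 3 arrays in each strain.

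Gene lists were tested with camera from limma at a preset correlation of 0.01 between genes, adjusted over the 29 lists of each contrast. An estimated correlation and fry were run beside it. The lists were corneal epithelium, corneal stroma keratocytes, corneal endothelium, collagens, proteoglycans and keratan sulfate enzymes, collagen processing and crosslinking, matrix remodelling and matricellular proteins, and human loci for central corneal thickness and keratoconus. They also covered TGF-beta and BMP signalling, Wnt signalling, cell cycle, redox and corneal crystallin enzymes, interferon-stimulated genes, antigen presentation, leukocytes, keratinization and surface barrier, cell junctions, immediate early and heat shock genes, circadian clock, oxidative phosphorylation and ribosomal proteins. Markers of other tissues were listed for lens, retina, pigment cells and iris epithelium, muscle, conjunctiva and limbus, blood and vessels, and nerve and Schwann cells, and a last list held genes that check the labels.

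Strain groups, contrasts, filter, pseudocount, gene lists and the rule for named genes were fixed before the data were examined. The rule took, in each contrast, the 6 highest and the 6 lowest log2 differences among called genes whose 3 arrays of a strain all lay above the 3 of the other. It added up to 2 called members of each list with the largest absolute difference, or up to 4 for the matrix lists and the human loci, and up to 2 members with the highest mean where none was called. Krt12, Kera, Lum, Dcn, Col1a1, Col5a1, Col8a2, Zfp469, Nnt and H2-Ea were named in every contrast where tested. Zfp469 was near the lower end of the scale on all 9 arrays and was not tested. Other genes were chosen after their values were seen, which is stated where they appear.

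The alternatives were no filter, a filter at the 70th percentile, quantile normalization, centring each array on its median, pseudocounts of 1 and 50, an intensity trend in the variance prior, array weights, the replicate number as a block, only the 6 arrays of the strains compared, a test against a fold of 1.2, plain probe sets whose identifiers carry no suffix for shared sequence, the mean of all probe sets of a gene, and leaving out each array in turn. The mean of all probe sets of a gene was run for gene lists only. A named gene was not tested under a filter or choice of probe sets that left it out. The model was tested on simulated data before use. Of probe sets changed by 1 on the log2 scale in simulated SJL arrays, 65.7% were called in SJL against KS and 70.1% in SJL against B6. At a change of 2 the shares were 97.0% and 95.5%, and at 0.5 they were 7.46% and 10.4%. Changes were planted in only 67 probe sets at 0.5, 67 at 1 and 66 at 2, with independent noise. That is a far smaller share than was called in the real contrasts with SJL, so the adjustment was stricter. The shares are therefore not the sensitivity of the real contrasts. Simulated false calls numbered 3 in SJL against KS, 2 in SJL against B6 and 1 in KS against B6, out of 22519 probe sets. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.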

Results

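Transcript levels in the central cornea were compared among 3 strains, with 3 arrays each of C57Bl/6J (B6), C57BLKS/J (KS) and SJL/J (SJL) mice. The series concerns central corneal thickness as a trait of inbred strains, so the contrast of SJL with KS set a thick cornea against a thin one. Thickness fell together with strain, so it cannot be told apart from any other difference between SJL and KS. The mice of a strain replicate the strain and not the thickness. Genes that mark the corneal epithelium and stroma were abundant in every strain. Krt12, the keratin of differentiated corneal epithelium, had an intensity of 28462 ± 777 in B6, 26808 ± 388 in KS and 26604 ± 628 in SJL (SD, n = 3). Kera, the corneal keratan sulfate proteoglycan keratocan, had 12626 ± 527, 11724 ± 516 and 11789 ± 447, and Lum, which encodes lumican, had 4684 ± 318, 4880 ± 77.2 and 5010 ± 282. None of Krt12, Kera, Lum, Col1a1 and Col8a2 was called by limma in any contrast.

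Arrays of a strain correlated at 0.982 to 0.994 across probe sets and arrays of different strains at 0.955 to 0.980. The first principal component, with 47.3% of the variance, set the 3 SJL arrays apart, and the second, with 25.6%, separated B6 from KS. Over the 22519 probe sets tested, 4374 (19.4%) differed among the strains by the moderated F-test of limma, and 7492 had an unadjusted p under 0.05. H2-Ea, a class II histocompatibility gene that is inactive in some haplotypes, was at 203 ± 46.7 in KS, 4.43 ± 0.0506 in B6 and 4.45 ± 0.0086 in SJL. The Y-linked gene Eif2s3y lay between 3280 and 4977 on all 9 arrays, and the 3 Xist probe sets lay at 8.67 or lower on all of them. Nnt averaged 3563 in SJL, 2294 in KS and 2494 in B6, but the position of its probes relative to any deletion is not known here, so it checks no label.

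Several transcripts of photoreceptors stood out on 1 array, KS replicate 3. On that array Gnat1, rod transducin, was at 2108, Sag at 1326, Pde6g at 720, Rcvrn at 456 and Crx at 114, and on the other 8 arrays Gnat1 lay between 4.72 and 9.39. Guca1a was at 1093 on that array but also at 386 to 440 on the others, and Prph2, Pde6a and Opn1mw were near the lower end of the scale on all 9. The mean of the retina list on the log2 scale was 9.26 on KS replicate 3 and 5.52 to 5.76 elsewhere. Without that array the calls numbered 2430 in SJL against KS and 823 in KS against B6. Without KS replicate 1 they numbered 2617 and 998, and without KS replicate 2 they numbered 2337 and 745. The drop was therefore not particular to KS replicate 3. B6 replicate 3 had the highest ratio of 3' to 5' control signal, with a log2 difference of 1.55 for Gapdh against 0.73 to 1.17 on the other arrays. Without it the calls numbered 1013 in KS against B6 and 2945 in SJL against B6. Those counts were 887 and 2806 without B6 replicate 1, and 1069 and 2904 without B6 replicate 2.

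**Figure D1:**
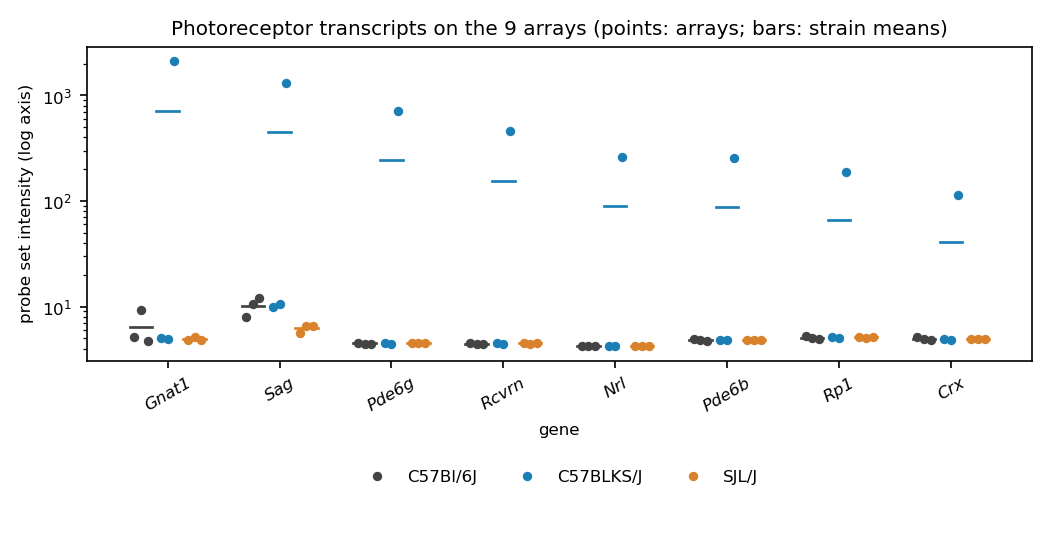
Intensity of 8 photoreceptor transcripts on a log axis, with 1 point per array and a bar at each strain mean of 3 arrays. KS replicate 3 lies far above all other arrays for each gene, with Gnat1 at 2108 and Crx at 114.

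In SJL against KS, the thick against the thin cornea, SJL gave far lower signal for several epithelial and matrix transcripts. Fmod, which encodes fibromodulin, a keratan sulfate proteoglycan that binds collagen fibrils, was at 449 ± 183 in SJL and 5907 ± 1474 in KS (log2 difference -3.74, adjusted p = 0.00018), and 5 of its 5 other tested probe sets were also lower. Krt15, a keratin of basal and limbal epithelial cells, was at 112 ± 124 against 8079 ± 1173 (-6.70), and Piezo2, a mechanically gated channel, at 45.3 ± 43.2 against 6876 ± 178 (-7.23). Sequence differences under the probes were not excluded for Krt15 and Piezo2. Fn1, fibronectin, went the other way, at 7052 ± 568 in SJL and 3191 ± 177 in KS (1.14, adjusted p = 0.00044). Limma called 3489 of 22519 probe sets, 1571 higher and 1918 lower in SJL, and 6492 had an unadjusted p under 0.05. Of the calls 1414 were at least 2-fold, 577 higher and 837 lower, and 399 at least 4-fold, 141 higher and 258 lower. Over genes, 747 were higher and 878 lower of 10956 tested. The other genes with the lowest differences were Apoc1 (-6.27), Trim12a (-6.14), Trim12c (-5.80) and Lgals7 (-5.40), which in SJL lay between 4.23 and 7.28 on average. A second probe set of Trim12c gave -0.08 with an adjusted p of 0.643. The highest were Nxpe4 (7.42), Ceacam10 (7.29), the mucosal chemokine Ccl28 (6.53), Gbp7 (6.10), Tmem45b (5.85) and Adh6a (5.05), with KS means of 16.5 or lower. Of the 74 genes named by rule in this contrast 61 were called, and 34 of those were called under every alternative that tested the gene.

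Proteoglycans, collagens and stromal keratocyte genes were called lower in SJL than in KS as lists by camera with the preset correlation, and most of their members were not called. Camera called 8 lists in this contrast, and 5 of 10 splits of the arrays, the real one included, gave as many. With an estimated correlation camera called 0 lists. These list calls are therefore weak evidence of a difference between the strains. Of 23 proteoglycans and keratan sulfate enzymes 3 were lower and 0 higher, with the same counts when adjusted over the list alone, and the median log2 difference was -0.20 (camera adjusted p = 0.0155). The adjusted p was 0.774 with an estimated correlation, and 5 were lower without B6 replicate 2. Beside Fmod the lower members were Omd, osteomodulin, at 5.29 ± 0.981 against 28.3 ± 13.7 (-1.27), and Dcn, decorin, at 14001 ± 618 against 18170 ± 1201 (-0.37, adjusted p = 0.0168). The Dcn call was lost without KS replicate 2 (0.0695), KS replicate 3 (0.0695) or SJL replicate 3 (0.0519). Of 24 collagens 3 were lower and 0 higher, also when adjusted over the list alone, with a median of -0.32 (camera adjusted p = 0.0178, and adjusted p = 0.774 with an estimated correlation), and the list was not called without KS replicate 2 (0.0807, median -0.21), while 5 members were lower without B6 replicate 3. Col3a1 was at 16.3 ± 4.76 against 95.5 ± 20.8 (adjusted p = 0.0104, or 0.0553 with no filter on dim probe sets). Col4a4 (-0.43) lost its call without KS replicate 1 or 2 or SJL replicate 2 or 3 (0.0646 to 0.121), and a second probe set of Col27a1 (-0.91) gave -0.25 with an adjusted p of 0.337. Of 21 stromal keratocyte genes 1 was higher and 5 lower, the same when adjusted over the list alone, with a median of -0.26 (camera adjusted p = 0.0308, and adjusted p = 0.774 with an estimated correlation). That list was not called without KS replicate 2 (0.0807), SJL replicate 1 (0.0518) or SJL replicate 3 (0.0735). Its lower members numbered 3 without B6 replicate 1, 2 without KS replicate 1, 2 or 3 and 1 without SJL replicate 3, and the higher one was not called without KS replicate 1 or 3 or SJL replicate 1.

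Other matrix lists were not called by camera as groups. Of 23 remodelling and matricellular genes 2 were higher and 3 lower (2 and 4 adjusted over the list alone, camera adjusted p = 0.143), with lower Thbs1, thrombospondin 1 (644 ± 218 against 1485 ± 203), lower Mfap4, a microfibril protein (1178 ± 113 against 2774 ± 485), and lower Timp3, a metalloproteinase inhibitor (986 ± 210 against 2267 ± 297). Of 21 collagen processing and crosslinking genes 0 were higher and 4 lower, also when adjusted over the list alone (0.170), among them Fkbp14 at 293 ± 15.5 against 454 ± 19.4 (-0.62). Of 38 human loci for central corneal thickness and keratoconus 0 were higher and 6 lower, also when adjusted over the list alone (0.0826). Tgfb2 was at 135 ± 39.6 against 288 ± 57.3 (-1.06), a call lost without KS replicate 2 (0.0534) or KS replicate 3 (0.0507). Ibtk was lower by its brighter probe set (-0.77) and not by its second (0.04, adjusted p = 0.864). In the same loci Col8a2 differed by 0.04 and Col5a1 by -0.68 (adjusted p = 0.144, called with array weights), while its other probe sets gave -1.44 (0.0477, called) and -1.03 (0.0501). Of 25 TGF-beta and BMP genes 2 were higher and 2 lower (2 and 5 adjusted over the list alone, 0.127), with Bmp7 at 305 ± 124 in SJL and 64.2 ± 23.4 in KS. Of 23 Wnt genes 0 were higher and 4 lower (1 and 4 adjusted over the list alone, 0.293), with Fzd1 at 806 ± 102 against 1270 ± 54.2.

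**Figure D2:**
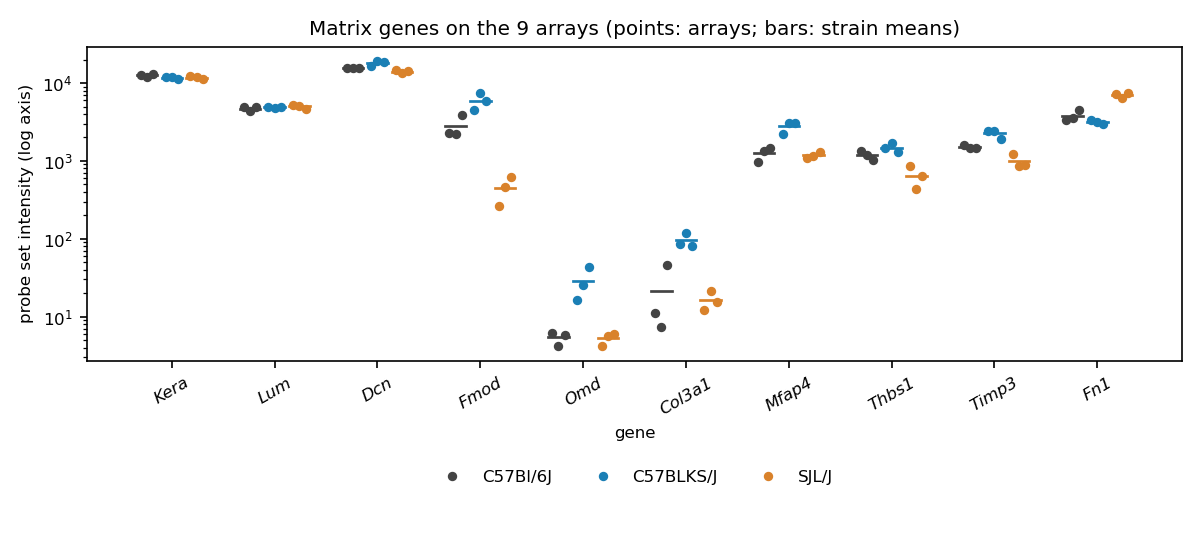
Intensity of 10 matrix genes on a log axis, with 1 point per array and a bar at each strain mean of 3 arrays. Lum overlaps among strains, Kera, which was not called, lies higher on the 3 B6 arrays than on the 3 KS arrays, Fmod has a mean of 449 in SJL, 2810 in B6 and 5907 in KS, and Fn1 has means of 7052, 3796 and 3191.

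Epithelial, endothelial and surface genes differed in part between SJL and KS. Of 13 endothelial genes 0 were higher and 5 lower (1 and 5 adjusted over the list alone), with a median of -0.30 (camera adjusted p = 0.0155, and adjusted p = 0.774 with an estimated correlation). The lower members numbered 2 without KS replicate 2 or 3, and 3 without B6 replicate 1, KS replicate 1, SJL replicate 2 or SJL replicate 3, the last with 1 higher. The 5 included the lactate transporter Slc16a1 (252 ± 7.76 against 675 ± 17.5) and Atp1b1, a subunit of the sodium pump (2668 ± 366 against 5625 ± 451), for which 3 of 3 other probe sets were also lower. Of 14 markers of conjunctiva and limbus 0 were higher and 6 lower (1 and 6 adjusted over the list alone), with a median of -0.52 (camera adjusted p = 0.0241, and adjusted p = 0.774 with an estimated correlation). With no filter on dim probe sets that median was 0.00 and the adjusted p 0.121, and 1 member was higher without KS replicate 2. Krt15 and Gpha2, a glycoprotein hormone subunit (173 ± 68.8 against 601 ± 153), were the lower members with the largest differences. Of 23 epithelial genes 3 were higher and 4 lower, also when adjusted over the list alone (camera adjusted p = 0.475), with Muc1, a membrane mucin, lower (135 ± 56.1 against 983 ± 231) and Cldn4, a claudin, higher (2408 ± 392 against 1046 ± 164). The Cldn4 call was lost without KS replicate 1 or 2 or SJL replicate 1 or 2 (0.0534 to 0.0722) and with no filter on dim probe sets (0.0855). Of 32 junction genes 6 were higher and 3 lower (7 and 4 adjusted over the list alone, 0.477), with Gjb6, a connexin, lower (97.8 ± 7.37 against 493 ± 134). The hemidesmosome genes Itgb4 (1984 ± 281 against 1056 ± 49.6) and Lama3 (4176 ± 499 against 2430 ± 138), chosen after their values were seen, were among its higher members. Of 15 keratinization genes 2 were higher and 3 lower, also when adjusted over the list alone (0.684), with Sbsn, suprabasin, lower (154 ± 51.5 against 444 ± 27.7) and, chosen after their values were seen, Spink5 (1493 ± 264 against 581 ± 151) and Krt1 (76.4 ± 3.12 against 42.0 ± 3.56) higher. Of 9 nerve and Schwann cell markers 0 were higher and 1 lower, also when adjusted over the list alone (0.770), the neurotrophin receptor Ngfr at 145 ± 24.6 against 658 ± 183.

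Interferon-stimulated genes were higher in SJL than in KS as a list, with 5 of 23 higher and 1 lower, the same when adjusted over the list alone, and a median of 0.38 (camera adjusted p = 0.0155, and adjusted p = 0.774 with an estimated correlation). Without SJL replicate 3 the median was 0.12 and the adjusted p 0.0735, with 3 members higher, as without KS replicate 2. The lower member was not called without B6 replicate 2, KS replicate 2 or 3 or any SJL replicate. Gbp2, an interferon-induced GTPase, differed by 2.79, and Xaf1 was higher by its brighter probe set (3.06) and lower by its second (-5.06). Of 26 cell cycle genes 0 were higher and 4 lower, also when adjusted over the list alone, with a median of -0.60 (camera adjusted p = 0.0178, and adjusted p = 0.793 with an estimated correlation), and the list was not called without SJL replicate 1 (0.164, median -0.26). Its lower members numbered 8 without SJL replicate 2, 2 without SJL replicate 1, and 1 without SJL replicate 3 or KS replicate 1, 2 or 3. The 13 retina markers had 1 lower member, also when adjusted over the list alone, and a median of -1.38 (camera adjusted p = 0.0178, and adjusted p = 0.774 with an estimated correlation), which was -0.21 without KS replicate 3. Without KS replicate 1 or KS replicate 2 that median was -2.03 and -2.02, and without SJL replicate 2 the retina list was not called (0.0631). Without KS replicate 1 or KS replicate 3 it had 2 lower members. The called member was Gnb1 (-0.65), a G protein subunit that is not limited to retina, and its second probe set was higher (0.54).

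Further lists were not called in SJL against KS. Counts higher and lower were 2 and 5 of 29 redox and crystallin enzymes (2 and 6 adjusted over the list alone, camera adjusted p = 0.337), with lower Gstm1 (2114 ± 62.2 against 3932 ± 386), 2 and 4 of 16 antigen presentation genes (0.475) and 1 and 1 of 13 leukocyte markers (0.415). They were 1 and 1 of 21 immediate early and heat shock genes (0.489), 0 and 1 of 15 clock genes (0.489), 0 and 0 of 28 oxidative phosphorylation genes (0.415) and 0 and 1 of 20 ribosomal proteins (0.437). Limma counted the same calls in these 6 lists when adjusted over the list alone. The clock member was Npas2 (41.6 ± 23.2 against 445 ± 275), and the ribosomal one Rpl14 (739 ± 95.3 against 2938 ± 75.4). Some clock genes varied widely within a strain, with Arntl at 236 to 1023 in KS, Per2 at 243 to 917 in B6 and Ciart at 38.1 to 244 in SJL. Clock itself lay between 3841 and 5488 on all arrays. Few calls in the clock list therefore do not show equal levels. Among markers of other tissues, counts were 2 and 1 of 3 for lens (0.475), 0 and 0 of 6 for pigment cells and iris (0.814), 0 and 0 of 6 for muscle (0.489), 0 and 0 of 1 for blood and vessels (0.379) and 1 and 1 of 6 for the label checks (0.770). The median of the label checks was 0.10 while their mean was -0.66.

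Several list calls in SJL against KS ended under other choices. With fry the stromal keratocyte (0.0568), collagen (0.134), interferon-stimulated (0.0810), cell cycle (0.261) and retina (0.168) lists were not called. Beside the proteoglycan, endothelial and conjunctival lists and the label checks, fry called corneal epithelium (0.00649), collagen processing (0.0297), redox (0.0119), antigen presentation (0.0408) and ribosomal proteins (0.0112), which camera did not call. With the mean of all probe sets of a gene the endothelial (0.0686), proteoglycan (0.0686), interferon-stimulated (0.132), cell cycle (0.0807), retina (0.0807) and conjunctival (0.126) lists were not called. Among plain probe sets this held for endothelial (0.0599), stromal (0.0880) and cell cycle genes (0.193), and with the stricter filter for stromal (0.0579) and retina genes (0.139). Dcn (adjusted p = 0.547) and Fkbp14 (0.0774) were not called against a fold of 1.2, and Tgfb2 (0.0560) was not called with no filter.

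The filter on dim probe sets also bore on the size of list differences in SJL against KS. With no filter the median was -0.12 for collagens, -0.09 for proteoglycans and -0.75 for retina markers, and the lower members numbered 1 for collagens, 1 for cell cycle and 3 for endothelium. With the stricter filter 1 collagen was lower and the retina median was -0.54. Among plain probe sets 2 endothelial and 2 cell cycle genes were lower. With a pseudocount of 50 the medians were 0.24 for interferon-stimulated genes and -0.79 for retina markers.

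**Figure D3:**
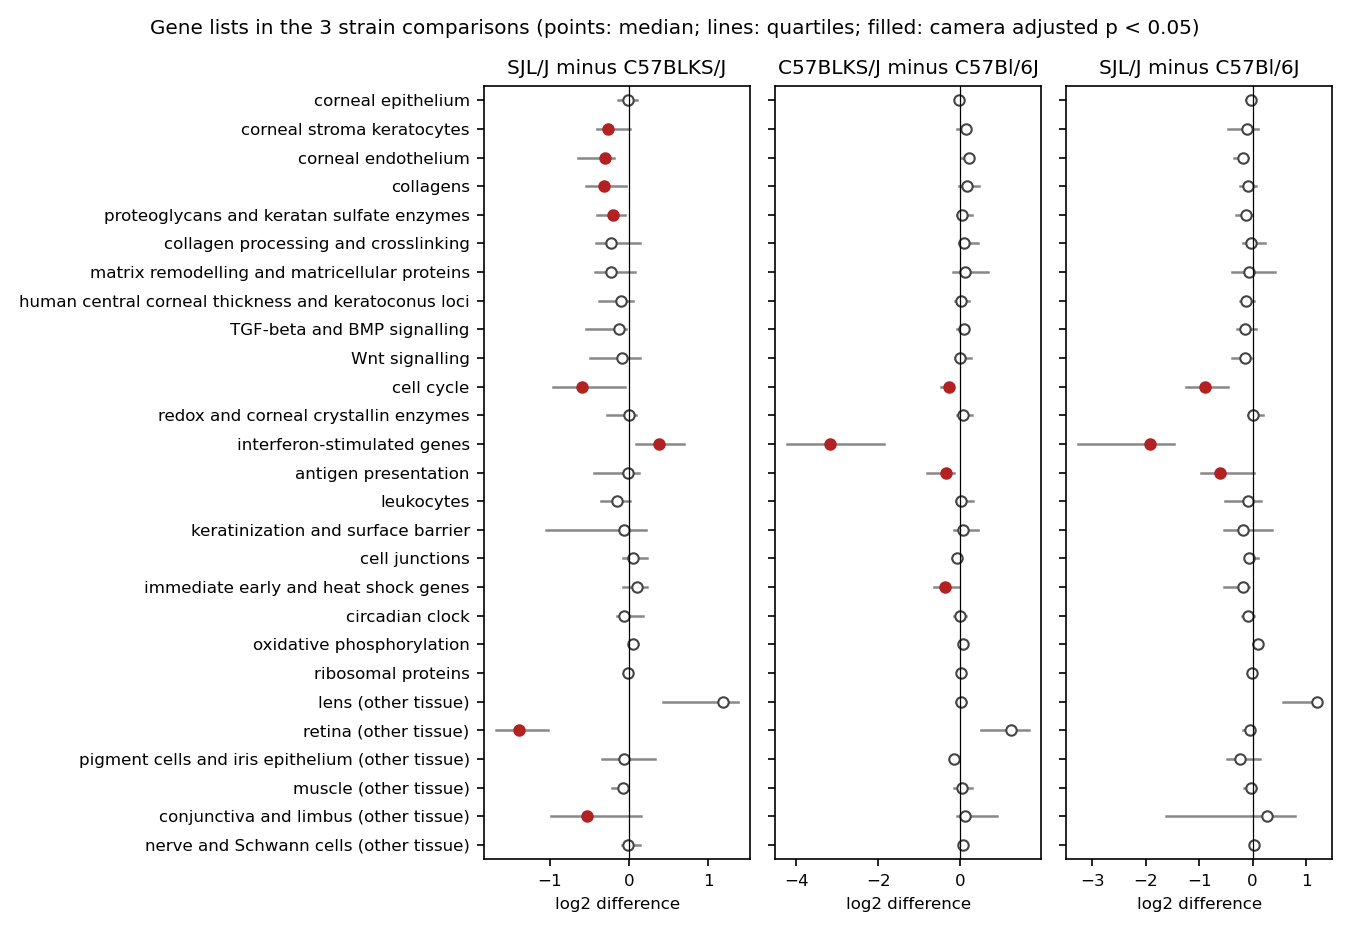
Median log2 difference of the tested members of gene lists with at least 3 of them, label checks apart (point), with its quartiles (line) in the 3 contrasts, in units of log2(intensity + 10). Filled points had a camera adjusted p under 0.05 with a preset correlation, 8 lists in SJL against KS, 4 in KS against B6 and 3 in SJL against B6.

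In KS against B6, genes induced by interferon were much lower in KS. Of 23 interferon-stimulated genes 22 were lower and 0 higher (23 lower when adjusted over the list alone), with a median log2 difference of -3.18 (camera adjusted p = 9.45e-37, and adjusted p = 0.198 with an estimated correlation). Ifi27l2a was at 149 ± 15.2 in KS and 8323 ± 1445 in B6 (-5.70), and Rsad2, an antiviral enzyme, at 4.93 ± 0.0326 and 791 ± 555 (-5.39). The member that limma did not call was Mx1, chosen after its values were seen, at 5.86 ± 0.361 and 110 ± 152 (-1.96, adjusted p = 0.251). Antigen presentation genes were lower in 7 and higher in 2 of 16 (10 and 2 adjusted over the list alone), with a median of -0.36 (camera adjusted p = 0.000503, and adjusted p = 0.625 with an estimated correlation). Among plain probe sets that list was not called (0.0546), 4 members were lower without KS replicate 3, and 1 was higher without B6 replicate 1 or 2 or KS replicate 1 or 2. Nlrc5, an activator of class I histocompatibility genes, was lower (4.66 ± 0.194 against 484 ± 310) and H2-Ea was higher (3.86). Leukocyte markers had 0 higher and 0 lower of 13 (1 higher when adjusted over the list alone, camera adjusted p = 0.827), with Cd68 at 612 ± 140 and 481 ± 57.7.

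**Figure D4:**
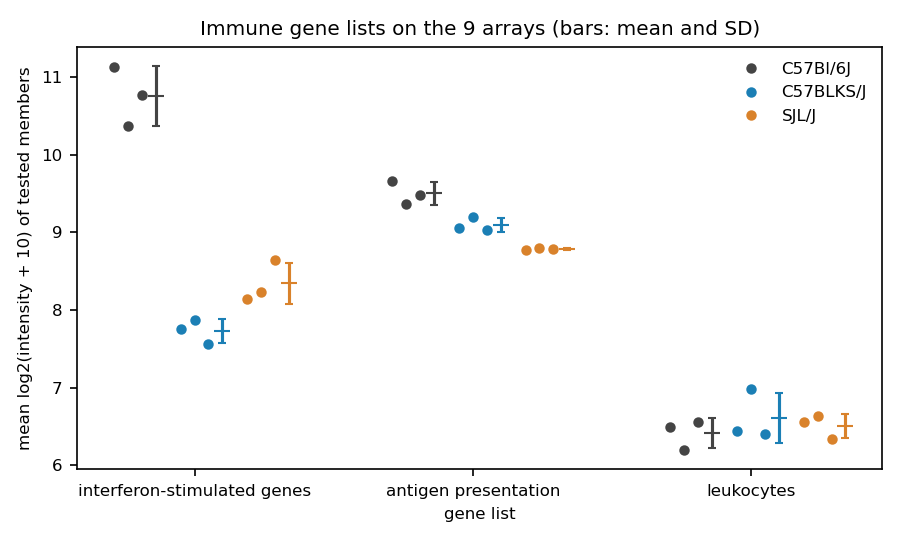
Mean log2(intensity + 10) of the tested members of 3 gene lists on each array (points), with the mean and SD of 3 arrays per strain beside them. The interferon-stimulated list averaged 10.8 in B6, 7.73 in KS and 8.34 in SJL.

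Fewer probe sets differed between KS and B6 than in the contrasts with SJL. Limma called 1286 of 22519, 655 higher and 631 lower in KS, with 4322 at an unadjusted p under 0.05. The count was 745 without KS replicate 2 and 823 without KS replicate 3. At least 2-fold were 265 higher and 362 lower, at least 4-fold 68 higher and 149 lower, and 371 genes were higher and 314 lower. The lowest differences were Pbp2 (-7.46), Gbp7 (-6.86), the killer cell receptor gene Klra8 (-5.89), Ripply3 (-5.77), Ifi27l2a and Adh6a (-5.52), all but Ifi27l2a near the lower end of the scale in KS. Whether sequence differences under the probes lowered these signals in KS was not tested. The highest were 6330403K07Rik (4.69), the cornified envelope gene Lce3f (723 ± 245 against 32.4 ± 11.4), E4f1 (3.87), H2-Ea, Plbd1 (1259 ± 121 against 92.1 ± 22.4) and the magnesium channel Trpm6 (330 ± 17.0 against 18.2 ± 3.56). Fst, follistatin, was lower in KS (92.7 ± 44.7 against 741 ± 227), and Gjb6 (2.27), Glo1 (11087 ± 550 against 6979 ± 429) and Rpl14 (1.61) were higher. Of the 69 genes named by rule 40 were called, and 20 of those were called under every alternative that tested the gene.

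No matrix list was called by camera in KS against B6, and fry called collagen processing (0.0368). Counts higher and lower were 3 and 0 of 24 collagens (7 and 1 adjusted over the list alone, camera adjusted p = 0.126), 2 and 0 of 23 proteoglycans (2 and 1, 0.618), 2 and 0 of 21 processing genes (4 and 0, 0.190) and 3 and 0 of 23 remodelling genes (5 and 0, 0.618). Mfap4 was higher in KS (2774 ± 485 against 1250 ± 262, adjusted p = 0.00832), and so was Omd (1.26), which was not called with no filter on dim probe sets (0.0635). The Col3a1 call (1.93, adjusted p = 0.0267) was lost without B6 replicate 1 or 2, any KS replicate or SJL replicate 3 (0.0502 to 0.114). The Postn call (232 ± 14.4 against 112 ± 21.9, adjusted p = 0.0296) was lost without B6 replicate 1 or 2 or any KS replicate (0.0657 to 0.112). Of 38 human loci 2 were higher and 0 lower, also when adjusted over the list alone (0.762), and Arhgap20 was at 103 ± 7.65 against 25.2 ± 1.48.

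Other lists were called lower in KS than in B6 by camera with the preset correlation. At least 4 lists were called in 7 of 10 splits of these arrays, the real one included. Of 21 immediate early and heat shock genes 0 were higher and 1 lower, also when adjusted over the list alone, with a median of -0.38 (camera adjusted p = 0.00650, and adjusted p = 0.918 with an estimated correlation), and the list was not called without B6 replicate 2 (0.0542), and its median was -0.25 without KS replicate 2. Without KS replicate 3, the array with photoreceptor transcripts, 4 members were lower and the median was -0.60, and the list mean on that array was 11.4 against 10.8 on each of the other KS arrays and 11.3 to 11.7 on B6 arrays. The called member of the list, the stress-induced factor Atf3 (-1.79, adjusted p = 0.0301), lost the call without B6 replicate 1 or 2, KS replicate 1 or 2 or SJL replicate 1 or 3 (0.0508 to 0.123). Of 26 cell cycle genes 0 were called in either direction, also when adjusted over the list alone, and the median was -0.29 (camera adjusted p = 0.0253, and adjusted p = 0.918 with an estimated correlation). That list was not called without B6 replicate 2 (0.0542), B6 replicate 3 (0.137, median -0.15) or KS replicate 2 (0.0609), and its median was -0.46 without B6 replicate 1. With fry neither the immediate early (0.192) nor the cell cycle list (0.509) was called, and among plain probe sets the cell cycle list was not (0.195). Without B6 replicate 2 the lists called numbered 2 rather than 4. In corneal epithelium, TGF-beta and BMP signalling, keratinization and the label checks, the median, the mean and the camera direction differed in sign. The retina markers had a median of 1.23 (camera adjusted p = 0.188), on which KS replicate 3 bore as described for its photoreceptor transcripts.

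In SJL against B6, interferon-stimulated genes were again lower than in B6. Of 23 members 20 were lower and 0 higher (22 lower when adjusted over the list alone), with a median of -1.92 (camera adjusted p = 5.10e-21, and adjusted p = 0.661 with an estimated correlation). Ifi27l2a was at 104 ± 0.777 against 8323 ± 1445 (-6.18), and Rsad2 at 12.4 ± 12.6 against 791 ± 555 (-4.94). Of 16 antigen presentation genes 1 was higher and 8 lower (1 and 9 adjusted over the list alone), with a median of -0.61 (camera adjusted p = 0.00165, and adjusted p = 0.826 with an estimated correlation), but not among plain probe sets (0.325, median 0.00). That median was -0.25 with no filter or the stricter filter, and -0.27 with the mean of all probe sets of a gene. H2-Ab1 was at 24.3 ± 3.48 against 88.2 ± 15.7, and Nlrc5 at 4.64 ± 0.00832 against 484 ± 310. Of 26 cell cycle genes 0 were higher and 6 lower (12 lower when adjusted over the list alone), with a median of -0.88 (camera adjusted p = 2.25e-05, and adjusted p = 0.826 with an estimated correlation), but not with fry (0.127). The lower members numbered 17 without SJL replicate 2, 10 without B6 replicate 1 and 3 without B6 replicate 2 or 3, with 2 when no filter was used, and the median was -0.51 without SJL replicate 1. The list mean was 9.51 on SJL replicate 2 and on B6 replicate 1, 8.29 on SJL replicate 1 and 10.1 on B6 replicate 3. B6 replicate 3 and SJL replicate 2 had the highest Gapdh 3' to 5' log2 differences, 1.55 and 1.17. Bub1b, a mitotic checkpoint kinase, was at 180 ± 74.7 against 486 ± 99.3, a call lost with no filter on dim probe sets (0.0536). The lists called numbered 3, but 5 without KS replicate 3 and 7 without SJL replicate 1. At least 3 lists were called in 8 of 10 splits of these arrays, the real one included.

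Limma called 3605 of 22519 probe sets in SJL against B6, 1783 higher and 1822 lower in SJL, with 6614 at an unadjusted p under 0.05. At least 2-fold were 605 higher and 876 lower, at least 4-fold 140 higher and 315 lower, and 918 genes were higher and 836 lower. The lowest differences were Pbp2 (-7.46), Krt15 (112 ± 124 against 11551 ± 1938), Piezo2 (45.3 ± 43.2 against 5249 ± 324), the interferon-inducible Mndal (-6.75), Trim12a (-6.68) and Trim12c (-6.32). The highest were Nxpe4 (7.08), Ceacam10 (6.87), Ccl28 (6.53), Tmem87a (6181 ± 541 against 141 ± 54.1), Tmem45b (4.86) and Ctnnd2 (883 ± 93.9 against 26.6 ± 20.6). Of the 76 genes named by rule 64 were called, and 30 of those were called under every alternative that tested the gene.

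Individual matrix, surface and signalling genes also differed between SJL and B6. Fmod was at 449 ± 183 against 2810 ± 969 (-2.65), with 5 of 5 other probe sets also lower, and Fn1 at 7052 ± 568 against 3796 ± 592 (0.90). Mgp, matrix Gla protein, was at 2211 ± 449 against 5622 ± 374 (-1.36), and Fst at 35.7 ± 15.0 against 741 ± 227 (-4.04). Bmp7 was higher (305 ± 124 against 55.9 ± 18.5), as were Arhgap20 (1.62) and the leukocyte integrin gene Itgam (61.8 ± 16.2 against 18.6 ± 4.50). Of 13 leukocyte markers 2 were higher and 2 lower (2 and 5 adjusted over the list alone, camera adjusted p = 0.655). C1qb, a complement gene chosen after its values were seen, was lower (248 ± 72.1 against 497 ± 73.6), a call lost without any B6 replicate, KS replicate 1 or SJL replicate 1 or 3 (0.0582 to 0.110). Krt4, a keratin of conjunctival epithelium, was at 4.09 ± 0.00702 against 108 ± 48.7, Ngfr at 145 ± 24.6 against 594 ± 56.8, Npas2 at 41.6 ± 23.2 against 455 ± 163 and Slc16a1 at 252 ± 7.76 against 567 ± 92.3. Muc4, a membrane mucin, was lower by its brighter probe set (-2.76) but not by its second (-0.34, adjusted p = 0.227). No matrix list was called by camera, and fry called proteoglycans lower (adjusted p = 0.0240). Counts higher and lower were 1 and 2 of 24 collagens (adjusted p = 0.467), 1 and 4 of 23 proteoglycans (0.0970), 2 and 4 of 23 remodelling genes (0.655) and 2 and 2 of 38 human loci (0.286). Adjusted over the list alone they were 1 and 2, 1 and 5, 2 and 4, and 2 and 2. The conjunctiva and limbus markers had 3 higher and 6 lower of 14 (6 and 6 adjusted over the list alone, 0.467), and their median of 0.26 and mean of -0.61 differed in sign. Median, mean and camera direction also differed in sign for remodelling, redox, leukocyte, junction and nerve lists.

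KS and SJL lay on opposite sides of B6 for 94 probe sets called in both contrasts. Over genes, 27 were higher in KS and lower in SJL than in B6, and 21 were lower in KS and higher in SJL. The named examples were chosen after their values were seen, apart from Apoc1. Higher in KS and lower in SJL were the apolipoprotein genes Apoe (log2 differences from B6 of 1.13 and -2.48) and Apoc1 (0.98 and -5.29), Otx1 (1.52 and -3.46), Fndc1 (1.36 and -3.17), Arhgap31 (2.07 and -2.45) and the interleukin antagonist gene Il1rn (0.91 and -1.97). Lower in KS and higher in SJL were Cyp24a1, which degrades active vitamin D (-1.87 and 1.57), and the actin bundling gene Fscn1 (-0.84 and 1.08). The calls in KS against B6 were lost for Apoc1 without KS replicate 1 or 3 (0.06 and 0.0749) and for Fscn1 without KS replicate 2 or 3 (0.0615 and 0.0547). Without B6 replicate 1, 2 or 3 the count of 94 was 54, 59 and 60, without KS replicate 1, 2 or 3 it was 60, 51 and 50, and without SJL replicate 3 it was 60.

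Both contrasts with B6 used the same 3 B6 arrays. Probe sets called higher in both KS and SJL numbered 267 (51.9 for independent lists of those sizes), and lower in both 362 (51.1). Higher in KS and lower in SJL were 56 (53.0 for independent lists), and lower in KS and higher in SJL 38 (50). In 20 simulations of unchanged groups against shared arrays, 0 probe sets were called in both. Those groups held no differences to call, so this 0 cannot say how many of the shared calls come from sharing the B6 arrays. The correlation of the log2 differences across probe sets, which are not independent replicates, was 0.397 and the simulated value 0.498. The covariance was 0.129 against 0.0189 simulated, a difference of 0.110. Part of the excess of calls in a shared direction may come from the B6 arrays, which are too few to split.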

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

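Tests chosen after the results were seen were the probe set with the next highest mean for named genes and the fits read without KS replicate 3 or B6 replicate 3 for their control transcripts, which are the planned fits that leave out each array. Quantile normalization, centring, pseudocounts of 1 and 50, the intensity trend and the 6-array fits left each count of probe sets within 1.5 times its value, and the median of all log2 differences stayed between -0.01 and 0.03 under each scaling. With array weights the calls numbered 9450 in SJL against KS, 2232 in KS against B6, 7364 in SJL against B6, 10501 for any strain and 218 on opposite sides of B6. The weights ran from 0.268 for SJL replicate 2 to 8.28 for SJL replicate 3 and their estimation stopped before convergence, and the cause of the higher counts was not tested. Against a fold of 1.2 the calls were 1796, 641 and 1840 in the 3 contrasts and 33 on opposite sides, by construction of a stricter test. With the filter at the 70th percentile, which leaves fewer probe sets, they were 2101, 742 and 2156, with 2659 for any strain, 57 on opposite sides and 5 lists in SJL against B6. With no filter they were 838 in KS against B6 and 47 on opposite sides, with 7 lists in KS against B6 and 7 in SJL against B6, and plain probe sets gave 62 on opposite sides and 2 lists in KS against B6. The cause of these changes in lists was not tested. The estimated correlation called 0 lists in each contrast, with lowest adjusted p of 0.774, 0.198 and 0.661, fry called 6 in SJL against B6, and the mean of all probe sets called 2 in SJL against KS.

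Leaving out each array in turn gave 2337 to 3643 calls in SJL against KS, 745 to 1452 in KS against B6, 2523 to 3674 in SJL against B6, 3080 to 4269 for any strain and 50 to 106 on opposite sides of B6. Called lists ranged from 6 to 9, from 2 to 5 and from 3 to 7 in the 3 contrasts. Of the called genes named by rule, 17 of 61, 17 of 40 and 18 of 64 lost their call without some array, where fewer arrays were fitted. Each named gene was compared, in the contrasts that named it, with its probe set of the next highest mean and among plain probe sets. Its further probe sets were not covered, so other reversals may exist. The difference reversed for Rrm2 in KS against B6 (1.57, for plain probe sets and for the next highest mean), Lrrk1 in SJL against B6 (-0.40 in both), Xaf1 in SJL against KS (-5.06), Ibtk in SJL against KS (0.0370) and SJL against B6 (0.0123), Gnb1 in the same contrasts (0.54 and 0.45) and Fzd2 in SJL against B6 (0.00201). The cause was not tested. The replicate block gave 3315, 1124 and 3509 calls, 4095 for any strain, 79 on opposite sides, and 8, 4 and 3 lists. Residuals of arrays with the same number correlated at -0.266 to 0.263, with 3 of 9 pairs over 0.1, and those with different numbers at -0.357 to 0.423, so the numbers did not pair the arrays. Low signal limits 54.6% of the values, which lay below 16.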

Other observations

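Tests chosen after the results were seen were the leukocyte test, the shuffled calls that replaced circular shifts along the chromosomes, the settings of neighbouring genes by distance, symbol stem, interferon list and equal numbers, and all genes named here outside the fixed rule.

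Krt13 and Krt18 differed among strains, and the genes in this paragraph were chosen after their values were seen. Krt13, a keratin of stratified mucosal epithelium, was at 3709 ± 553 in SJL, 12120 ± 356 in KS and 12035 ± 1039 in B6, with log2 differences of -1.72 from KS and -1.70 from B6 (limma adjusted p = 3.57e-05 and 3.61e-05). Krt18, a keratin of simple epithelium, was at 401 ± 12.5 in KS against 104 ± 3.24 in B6 and 198 ± 49.3 in SJL (limma adjusted p = 0.000164 and 0.0027). The epithelial keratin genes Krt12, Krt6a and Krt6b were not called in any contrast. Krt5 and the abundant corneal genes Aldh3a1, Tkt and Pax6 differed by less than 0.06 in each contrast. Cd74, the class II chaperone, was at 418 ± 28.0 in SJL, 695 ± 157 in KS and 872 ± 18.2 in B6.

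The interferon-stimulated list averaged 10.8 ± 0.383 in B6, 7.73 ± 0.155 in KS and 8.34 ± 0.268 in SJL on the log2 scale (SD, n = 3). Fewer leukocytes in KS would lower their markers, of which 13 of the 31 with a probe set were tested. The median difference of the 13 was 0.02 with a bootstrap 95% interval of -0.10 to 0.30. The limit for that interval, set after the results were seen, was -1. The bootstrap resampled genes and not mice, so its interval leaves out the spread between mice. By limma, which uses that spread, 0 of the 13 were called lower in KS, though 3 arrays per strain can miss small changes. For the markers tested, these values argue against fewer leukocytes in KS as the whole cause. The leukocyte test did not cover SJL. Without B6 replicate 3, the array with a high 3' to 5' ratio, 21 of 22 called members of the interferon list remained lower. This argues against that array as the whole cause. Of the list 22 of 23 members were lower in KS, against 314 of 10956 genes tested. These counts are the pattern itself, so they cannot test its cause. Sequence differences under the probes stay open. Of 10 other probe sets of the called members, 8 were also lower in KS and 1 higher. The exact 95% lower bound of the share lower, 44.4%, fell short of its limit of 50%, so the planned test could not decide. A genotype effect and an exposure of the B6 animals cannot be told apart because strain and animals fall together, and the SD between B6 arrays was 2.46 times that between KS arrays.

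Large losses in SJL may reflect sequence differences under the probes, since several transcripts fell to the lower end of the scale. Of partner probe sets of the same gene, 74 of 132 (56.1%) were also called lower for probe sets at least 4-fold lower in SJL than in B6, and 45 of 68 (66.2%) were also called higher for those at least 4-fold higher. The one-sided Fisher exact p for a lower share among losses was 0.109, so the planned test left probe sequence open, and no probe sequences were used here. Pairs were counted per probe set, so a gene with several changed probe sets could enter more than once. The pairs were thus not independent, although the Fisher test treats them so. Strain differences in transcription stay open beside it.

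Genes called in KS against B6 lay next to one another more often than shuffled calls, with 92 adjacent pairs against 42.4 (ratio 2.17, permutation p = 1e-04, the smallest that 10000 shuffles can give), as they did in SJL against KS (1.39) and SJL against B6 (1.5), or 1.63 and 1.68 with equal numbers of genes, each also at 1e-04, while the planned circular shifts kept nearly all pairs together and could not test this. Paralogs with shared probes are argued against as the whole cause by called pairs 6 to 20 tested genes apart, with a ratio of 1.44, and by adjacent pairs with different symbol stems, with 1.88. Blocks of other ancestry in KS are a candidate explanation, in line with that 1.44 against 1.08 in SJL against B6 (also at 1e-04) and with 89 of 344 windows of 30 tested genes without a call where 49.9 would follow from scattered calls. Coexpressed neighbourhoods stay open, since the ratio of KS to SJL was 1.33, under its limit of 1.5, and with 681 genes in each contrast the ratios were 1.44 and 1.21. The densest windows, with 12 called genes each, ran from Kank3 to H2-Ea and from Mansc1 to Mgst1.

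Other splits of the arrays were fitted to ask how often they give as many calls as the strains. Every other split of 6 arrays set unequal numbers of each strain against each other, so it kept part of the strain difference. In SJL against KS 1 of the 10 splits of 6 arrays, the real one, gave 3489 calls and the highest other 0, in KS against B6 1 of 10 gave 1286 and the highest other 0, and in SJL against B6 1 of 10 gave 3605 and the highest other 1. With 10 splits no share under 0.05 can be reached. Called lists numbered 8 in SJL against KS (5 of 10 splits, the real one included, gave as many, highest other 13), 4 in KS against B6 (7 of 10, highest other 8) and 3 in SJL against B6 (8 of 10, highest other 6). The medians of the other splits were 6, 5 and 3 lists. These splits carried part of the strain difference, so they are no baseline free of it. The number of lists called at the preset correlation did not set the strains apart from them, and such a count cannot weigh a single list. For any strain, 1 of 100 drawn splits of the 9 arrays gave 4374 calls, the real one, and the highest other was 1829, so chance was excluded at that share. The 2 drawn splits that kept SJL whole gave the most calls among the others, and the rest gave at most 389, which points to the SJL arrays as the main structure. On opposite sides of B6, 1 of 100 gave 94 and the highest other was 0, but the other splits had a median of 0 calls for any strain, which left little to overlap. The 56 higher in KS and lower in SJL and the 38 the other way stood against 53.0 and 50 for independent lists, so chance overlap of the lists was not excluded.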
